A study of Mus musculus with 9 samples.

How the data were processed

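RNA from sorted cells was measured on 9 gene expression arrays: 3 of Ly6C-high microglia, 3 of Ly6C-low microglia and 3 of spleen monocytes from C57BL/6 mice. Per the labels' protocols, brains were perfused, digested and enriched for leukocytes on Percoll before the sort, RNA integrity was high in all samples, and cDNA was made, fragmented and biotin-labelled with whole-transcript kits for Affymetrix arrays. The authors deposited 1 table of log2 intensities with a column per array. RMA and oligo are named in the submitters' processing notes without versions. Background, normalization and summarization settings and the genome build are not given in the sources used here. The deposited log2 values ran from 2.54 to 13.81, with array medians of 5.83 to 5.96, and no value was missing. The interquartile range was 2.24 in Ly6C-high replicate 1 and 2.62 to 2.91 in the other arrays, so the arrays had not been forced to identical distributions over these probe sets. Differences of dim genes can be compressed in RMA values, and scaling arrays of different cell types to a common distribution can shift genes that did not change.

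The table holds 34760 probe sets. The platform annotation gives 21640 of them 1 gene symbol, 1321 several and 11799 none in the table used here. Gene IDs of 21553 probe sets were found in the RefSeq gene table, which changed 0 symbols, and 2 list symbols were matched through older names. Genes with several probe sets (954) were represented by the probe set with the highest mean over all 9 arrays, which left 19937 genes. No gene was named from a probe set with several symbols, and no coordinates are given because the build of the array design is not stated.

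Values were used as deposited, with no further scaling. limma 3.58.1 in R 4.3.3 (lmFit and eBayes) fitted the 3 group means to all 9 arrays, and the 3 contrasts were tested with Benjamini-Hochberg adjustment over all genes at 0.05, two-sided. Every adjusted p of a gene is from this limma fit. The 30 gene lists were tested with limma's camera, a preset inter-gene correlation of 0.01 and adjustment over the 30 lists of a contrast, with an estimated correlation and with fry as alternatives. Only 4 list calls, all of Ly6C-low microglia against monocytes, held with an estimated correlation: homeostatic microglia, nonclassical monocytes, B cells and interferon response. List members were also counted past the threshold over all genes and adjusted over the list alone. Some list members were not analysed here, and each list's number of measured genes is given. The lists cover 15 cell types, including those a brain or spleen sort could hold (homeostatic microglia, classical and nonclassical monocytes, border-associated macrophages, neutrophils, T, B, NK and dendritic cells, brain endothelium, pericytes and smooth muscle, astrocytes, oligodendrocytes, neurons, erythroid cells and platelets). The others cover cell division, stem and progenitor genes, antigen presentation, interferon response, disease-associated microglia, inflammatory genes, immediate early genes, complement, lysosome, TGF-beta, migration, CSF and IL-1 signalling, glycolysis and cholesterol synthesis. The lists, the tests and the naming rule were fixed before the data were examined.

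For each contrast the text names the 12 genes with the largest and the 12 with the smallest log2 fold change among those with an adjusted p under 0.05, with arrays of the groups that do not overlap, a higher group mean at or above the median of all gene means (6.13) and no predicted or clone-based symbol, plus up to 4 members of each list with the largest absolute change and the sort antigens. Genes named outside this rule were chosen after their values were seen: between the microglia groups Cldn5, Cdh5, Cd40, Btg2, Ifitm3, Aurkb, Gata2, Mecom, Myc, Meis1, Cd79b, Cxcr4 and Pfkl, and against monocytes Trem2, Csf1r, Klf2, Cx3cr1, Il34 and Stard4 where they were not already named by it. A kappa variable segment of the immunoglobulin genes met the rule and is given without its symbol.

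The position of Ly6C-high microglia used genes with an adjusted p under 0.05 and at least a 4-fold difference between Ly6C-low microglia and monocytes. It was set beside 100 simulated draws in which all 9 arrays were redrawn and the Ly6C-high group was given the Ly6C-low mean. The code was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. With 1 spread per gene in all groups, the Ly6C-high against Ly6C-low fit on 19937 genes recovered 57 of the 2-fold and 87 of the 4-fold genes, with 11 false calls among 160. A simulation with each group's own spread was added after the former was seen. With each group's own spread per gene, which is larger in Ly6C-high arrays than the pooled estimate assumes, it recovered 56 and 93. There were 108 false calls among 264 (40.9%), out of 19719 unchanged genes. The same simulation gave 95 false calls among 250 (38%) for Ly6C-high microglia against monocytes, and 15 among 176 (8.5%) for Ly6C-low microglia against monocytes. Counts that involve Ly6C-high arrays therefore hold more false calls than the threshold states.

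Alternatives planned at the same time were median centring, quantile normalization, cyclic loess, leaving out dim genes, the mean of a gene's probe sets, trend and robust eBayes, array weights, fits of 2 groups only, an unmoderated test, a 2-fold minimum, replicate blocks by the number in the title or in the description, and leaving out each array. After seeing the data, 2 were added: leaving out both Ly6C-high replicate 2 and Ly6C-low replicate 3, and 1 variance per group. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.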

Results

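The series profiled sorted mouse brain microglia on gene expression arrays, with spleen monocytes beside them. Brain leukocytes of C57BL/6 mice were sorted with antibodies to CD45, CD11b, F4/80, Ly6C and MHC class II, and the microglia were divided by surface Ly6C. Ly6C is a surface antigen of inflammatory monocytes that is also known in brain endothelium. There were 3 arrays of Ly6C-high microglia, 3 of Ly6C-low microglia and 3 of spleen monocytes. The submitters' labels call the Ly6C-low cells bulk microglia, and the series title speaks of a specialised cell subset that maintains and regenerates microglia. Values are on the log2 scale, as mean ± SD with n = 3 arrays per group unless said otherwise, and fold changes carry their standard error (SE). The number of arrays limits the precision. The labels do not say whether the replicates of a group came from separate animals, so p-values measure the spread between these samples, which may be technical. The Ly6C-high arrays were less alike than the others: correlations between arrays across all probe sets ran from 0.872 to 0.924 within Ly6C-high microglia, from 0.967 to 0.980 within Ly6C-low microglia and from 0.978 to 0.983 within monocytes. The median SD per gene was 0.27, 0.14 and 0.11 in that order.

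The transcripts of the sort antigens were read in every group. The 2 probe sets for Ly6C are each annotated to both Ly6c1 and Ly6c2, so neither gene can be named. Probe set 10429568 stood at 12.44 ± 0.05 in Ly6C-high microglia, 8.80 ± 1.66 in Ly6C-low microglia and 10.34 ± 0.16 in monocytes, and probe set 10429573 at 11.97 ± 0.10, 8.64 ± 1.32 and 11.66 ± 0.03. Both were higher in Ly6C-high than Ly6C-low microglia (log2 fold change 3.64 ± 0.69, adjusted p = 0.0131, and 3.33 ± 0.55, adjusted p = 0.0070). The Ly6C-low arrays ranged from 10.39 in replicate 1 to 8.94 in replicate 2 and 7.07 in replicate 3 on the former probe set. The other antigens pointed the other way. Adgre1, which encodes F4/80, was 6.70 ± 0.62 in Ly6C-high against 10.18 ± 0.26 in Ly6C-low microglia (log2 fold change -3.48 ± 0.28, adjusted p = 1.20e-04), and Itgam, which encodes CD11b, 8.62 ± 0.77 against 11.44 ± 0.08 (-2.82 ± 0.32, adjusted p = 6.65e-04). Ptprc, which encodes CD45, was 8.55 ± 1.26 against 10.02 ± 0.30, a difference that did not pass the test (adjusted p = 0.101), with Ly6C-high replicates at 8.02, 9.99 and 7.65. H2-Ab1, an MHC class II chain, was lower in Ly6C-high microglia by a smaller amount (-0.84 ± 0.17, adjusted p = 0.0109). Against monocytes, Ly6C-high microglia were lower in Ptprc (-2.99 ± 0.52, 7.94-fold, adjusted p = 0.0049), Itgam (-1.89 ± 0.32, 3.72-fold, 0.0045), Adgre1 (-2.26 ± 0.28, 4.78-fold, 8.87e-04) and H2-Ab1 (-3.97 ± 0.17, 15.7-fold, 4.70e-06). Ly6C-low microglia were higher than monocytes in Adgre1 (1.22 ± 0.28, adjusted p = 0.0209) and lower in H2-Ab1 (-3.13 ± 0.17, 1.17e-05), while Ptprc and Itgam did not pass (0.0963 and 0.103).

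The comparison of Ly6C-high with Ly6C-low microglia asks how the subset differs from bulk microglia. The Ly6C-high arrays carried high levels of genes known from the blood-brain barrier endothelium and low levels of the genes that mark homeostatic microglia. Group names follow the labels, and bulk RNA does not tell which cells a transcript came from. Brain endothelial cells in the Ly6C-high sort are a candidate source, taken up further below. Of the 19 measured brain endothelium genes 18 were higher and none lower, with a median log2 fold change of 3.20, and of the 23 measured homeostatic microglia genes 22 were lower and none higher, with a median of -2.55. In all, 3080 of 19937 genes passed an adjusted p of 0.05, 895 higher and 2185 lower in Ly6C-high microglia, and 1845 of these differed by at least 2-fold. The arrays of the groups did not overlap for 30.1% of all genes, against 10% by chance.

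The 12 genes that rose most were led by Car4, a carbonic anhydrase of brain capillaries, at 11.49 ± 0.16 against 5.83 ± 0.62 (log2 fold change 5.66 ± 0.27, 50.7-fold, adjusted p = 1.48e-05). Emcn, an endothelial sialomucin, followed with 11.21 ± 0.24 against 6.03 ± 0.39 (5.18 ± 0.21, 36.3-fold, adjusted p = 1.15e-05). Several of the rest are barrier transporters: Slco1a4 (5.02 ± 0.63) and Slco1c1 (4.80 ± 0.39), which carry organic anions and thyroid hormone, the lipid transporter Mfsd2a (4.76 ± 0.23) and the organic anion transporter Slc22a8 (4.37 ± 0.25). Itm2a rose by 5.03 ± 0.41, the Wnt inhibitor Apcdd1 by 4.40 ± 0.18, Prom1, which encodes CD133, by 4.37 ± 0.26, the guidance cue Sema3c by 4.36 ± 0.25 and the proteoglycan Spock2 by 4.34 ± 0.29 on the log2 scale. Ctla2a was also among them (4.82 ± 0.48), and its close relative Ctla2b may share its probes. Adjusted p-values of these 12 genes ran from 1.15e-05 to 0.0011. Within the endothelium list, Flt1, a VEGF receptor, rose by 3.84, the tight junction gene Cldn5 by 3.19 and the endothelial cadherin Cdh5 by 3.20. The list passed the set test (camera adjusted p = 1.89e-20), and 18 members also passed when adjusted over the list alone. With an estimated correlation its adjusted p = 0.198. The Ly6C-low arrays themselves differed in this list, with list means of 7.78, 7.20 and 6.43 in replicates 1, 2 and 3 against 10.1 to 10.6 in the Ly6C-high arrays and 6.39 to 6.42 in monocytes.

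**Figure D1:**
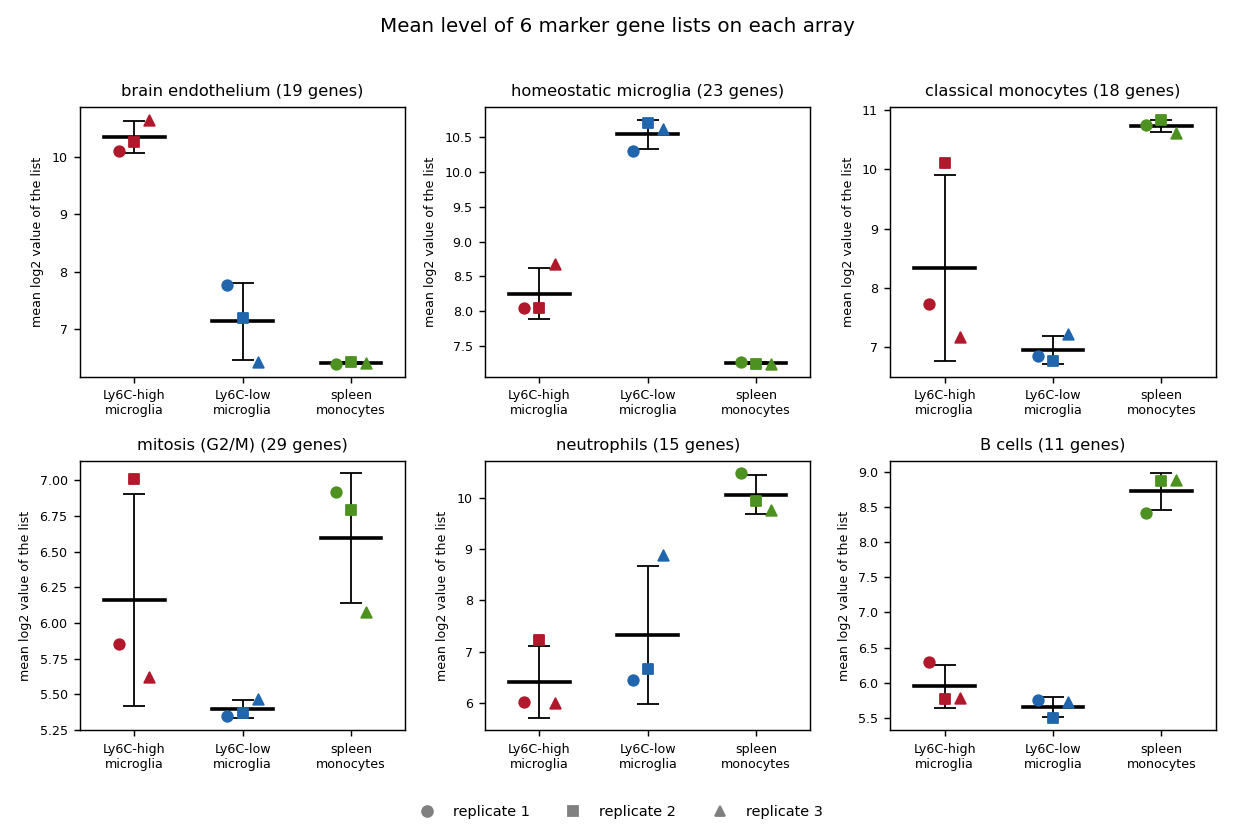
Mean log2 value (vertical axes) of 6 marker gene lists on each of the 9 arrays, by group, with marker shapes for replicates, thick lines for group means and bars for the SD of 3 arrays. The brain endothelium list was at 10.1 to 10.6 on the Ly6C-high arrays, and the classical monocyte list at 10.11 on Ly6C-high replicate 2 against 7.72 and 7.18 on replicates 1 and 3.

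The genes that fell most included the fatty acid receptor Gpr84, at 6.49 ± 0.71 against 10.76 ± 0.38 (-4.27 ± 0.50, 19.3-fold lower, adjusted p = 7.54e-04), and Gal3st4, a sulfotransferase (-4.00 ± 0.20, adjusted p = 1.66e-05). Olfml3 (-3.69 ± 0.44), the complement receptor C3ar1 (-3.69 ± 0.66) and Fcrls (-3.66 ± 0.38) are known microglia genes. Tagap (-3.94), the phosphodiesterase Pde3b (-3.93), the glycosyltransferase Mgat4a (-3.83), Plxdc2 (-3.82), Tubgcp5 (-3.81) and the transporter Abcc3 (-3.70) completed the 12, with Retnlg (-3.83), a neutrophil gene that was highest in Ly6C-low replicate 3, with 8.02 and 9.01 in replicates 1 and 2. In the homeostatic microglia list, Tmem119 stood at 8.67 against 11.94 (-3.27) and the lectin Siglech fell by 3.15 on the log2 scale. Its camera adjusted p was 4.06e-20, 22 members passed when adjusted over the list alone, and with an estimated correlation adjusted p = 0.198. Of 16 complement and phagocytosis genes 13 fell (median -2.29, camera adjusted p = 3.67e-10), among them C3ar1, the Fc receptor Fcgr1 (-3.10), Trem2 (-2.94) and Mertk (-2.94). Of 20 lysosome genes 15 fell (median -1.62, adjusted p = 1.98e-12), among them the cholesterol transporter Npc1 (-2.37), the cathepsins Ctsz (-2.37) and Ctss (-1.95) and the hexosaminidase subunit Hexa (-2.10). Of 22 inflammatory genes 15 fell (median -1.87, adjusted p = 5.54e-09), with the chemokines Ccl12 (-3.32) and Ccl7 (-2.59), the cytokine Tnf (-2.85) and the NF-kB inhibitor Tnfaip3 (-2.50). Adjusted over the list alone, 15 complement, 19 lysosome and 16 inflammatory genes were lower and 1 inflammatory gene higher. With an estimated correlation the 3 lists had adjusted p = 0.198, 0.260 and 0.198.

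In 5 further lists called lower, fewer members passed. In the TGF-beta pathway 7 of 12 genes fell (median -1.05, camera adjusted p = 2.67e-05), led by the receptor Tgfbr1 (-2.59) and Skil (-2.25), and of 20 genes of disease-associated microglia 9 fell (median -0.93, adjusted p = 8.91e-06), with Timp2 at -2.85 and the tetraspanin Cd9 at -2.40. Of 13 border-associated macrophage genes 4 fell, Mrc1 (-2.83), Stab1 (-2.07), Maf (-1.70) and Ms4a7 (-1.46) (list adjusted p = 0.0027). Of 11 MHC class II and costimulation genes 3 fell, Cd86 (-3.10), Cd74 (-1.37) and H2-Ab1, and Cd40 rose by 0.76 (list adjusted p = 0.0300). Of 21 immediate early and heat shock genes 3 fell, Klf6 (-1.11), Rhob (-0.90) and Btg2 (-0.87) (list adjusted p = 0.0060). With an estimated correlation these 5 lists had adjusted p = 0.198, 0.198, 0.562, 0.599 and 0.599. Adjusted over the list alone, 9, 12, 4, 6 and 5 members were lower, and 1 disease-associated and 1 MHC class II gene higher. The MHC class II call ended without Ly6C-high replicate 1 (median -0.59, adjusted p = 0.0833), Ly6C-high replicate 3 (-0.66, 0.0681) or Ly6C-low replicate 2 (-0.59, just above the threshold), and the immediate early call without Ly6C-high replicate 1 (-0.41, 0.0814). Both calls also ended under quantile normalization and cyclic loess. The calls of Cd86, Rhob and Ms4a7 were lost in 10 of 22, 10 of 22 and 9 of 21 alternatives.

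The lists of classical monocytes and of cell division were called higher in Ly6C-high microglia with few members past the threshold, and their list means were highest in replicate 2. The classical monocyte list of 18 genes had a median log2 fold change of 1.25 (camera adjusted p = 0.0015, 0.599 with an estimated correlation), and 3 genes passed over all genes and over the list alone, fibronectin Fn1 (3.03), S100a4 (2.99) and the interferon-induced Ifitm3 (2.26). Fn1 (10.75, 11.60 and 10.97) and Ifitm3 (11.51, 12.38 and 11.81) were high in all 3 Ly6C-high replicates, and S100a4 was at 9.98, 11.04 and 7.12. The calls of Fn1 and Ifitm3 thus did not follow the list mean given below and do not single out monocytes as their source. The S100a4 call was lost in 13 of 22 alternatives. The list mean was 10.11 in Ly6C-high replicate 2 and 7.72 and 7.18 in replicates 1 and 3, against 6.77 to 7.22 in Ly6C-low microglia and 10.6 to 10.8 in monocytes. Without Ly6C-high replicate 2 the median was 0.36 and the call ended (adjusted p = 0.158). Of 29 mitosis genes 2 rose, Kif23 (1.71) and the kinase Aurkb (0.73, a call lost in 15 of 22 alternatives), and 1 when adjusted over the list alone. Their median was 0.73 (camera adjusted p = 6.99e-05, 0.624 with an estimated correlation), and 0.29 without Ly6C-high replicate 2 (adjusted p = 0.0288). The mitosis list mean was 7.01 in that replicate, 5.86 and 5.62 in the others, 5.35 to 5.47 in Ly6C-low microglia and 6.08 to 6.92 in monocytes. Of 27 DNA replication genes 2 rose, Tipin (1.13) and Mcm4 (0.95), with a list median of 0.23 (adjusted p = 0.0398, 0.757 with an estimated correlation). That call ended without Ly6C-high replicate 2 (median -0.03, adjusted p = 0.743), Ly6C-low replicate 1 (0.25, 0.0707) or Ly6C-low replicate 2 (0.22, just above the threshold). It also ended under median centring, with the description number as a block and without Ly6C-high replicate 2 and Ly6C-low replicate 3 together. Interferon response genes were mixed: 7 of 21 rose, among them Rtp4 (2.04), Xaf1 (1.81) and Irf7 (1.44), and the chemokine Cxcl10 fell by 2.27 on the log2 scale (list median 0.49, adjusted p = 0.0082, 0.341 with an estimated correlation). The interferon call ended without Ly6C-high replicate 2 (median 0.24, adjusted p = 0.102), and without that array and Ly6C-low replicate 3 together. The gene call of Irf7 was lost in 9 of 22 alternatives. Over their lists alone, 2 replication genes and 8 interferon genes were higher and 1 interferon gene lower.

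The stem and progenitor list of 20 genes had 5 higher and 3 lower members (median 0.21, camera adjusted p = 0.0398), the same numbers when adjusted over the list alone. With an estimated correlation its adjusted p = 0.200, and the call ended without Ly6C-high replicate 2 (median 0.33, adjusted p = 0.0908) or replicate 3 (0.20, 0.0809), under median centring and without Ly6C-high replicate 2 and Ly6C-low replicate 3 together. The higher ones were Prom1 (4.37), Erg (2.59), the intermediate filament nestin Nes (2.21), Gata2 (2.12) and Mecom (2.08), and the lower ones Runx1 (-2.58), Myc (-1.96) and Meis1 (-0.68, a call lost in 10 of 21 alternatives). Erg and Gata2 are transcription factors known from endothelium as well as from blood progenitors, and Prom1 and Nes are also known in brain vessels. Of 13 pericyte and smooth muscle genes only Vtn passed (2.28, also over the list alone), with a list median of 0.79 (adjusted p = 0.0039, 0.599 with an estimated correlation).

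The other 14 lists had no call between the microglia groups. Neutrophil genes had 2 of 15 lower, Csf3r (-2.38) and Retnlg, with a list mean of 8.87 in Ly6C-low replicate 3 against 6.44 and 6.66 in replicates 1 and 2. CSF and IL-1 genes had 4 of 11 lower, Csf3r, the receptors Csf1r (-2.37) and Csf2rb (-1.90) and the ligand Csf1 (-0.91), with a list adjusted p of 0.0979. In the rest few members passed: 1 up and 1 down of 12 nonclassical monocyte genes (Pglyrp1 3.77, Dusp16 -1.31), 1 down of 13 T cell genes (Il7r -3.16), 1 up and 1 down of 11 B cell genes (Ebf1 3.21, and Cd79b -0.78, with an adjusted p just under the threshold), 1 down of 13 NK cell genes (Klrd1 -1.40), 0 of 9 dendritic cell genes, 1 up and 1 down of 11 astrocyte genes (Gja1 2.32, Slc1a3 -2.05), 1 up and 1 down of 13 oligodendrocyte genes (Mal 0.96, Mag -0.74), 2 down of 13 neuron genes (Eno2 -0.86, Snap25 -0.76) and 2 down of 9 erythroid and platelet genes (Itgb3 -1.10, Gp9 -0.99). Of 14 migration genes 2 rose (S1pr1 2.29 and Cxcr4) and 2 fell (Selplg -2.24, Cx3cr1 -1.85), of 12 glycolysis genes 1 rose (Slc2a1 1.61, also in the endothelium list) and 2 fell (Hk2 -2.12, Pfkl -0.49), and of 16 cholesterol synthesis genes 2 rose, Stard4 (1.25) and Fdps (0.72), with a list median of -0.38. Adjusted over the list alone, 4 nonclassical monocyte, 4 migration and 4 CSF and IL-1 genes were lower, 1 CSF and IL-1 gene and 2 glycolysis genes higher, and the other counts were the same. Of these genes Cd79b lost its call in 15, Csf2rb in 14, Fdps in 13 and Mal in 11 of 22 alternatives. For nonclassical monocytes, T cells, NK cells, dendritic cells, oligodendrocytes, neurons, and erythroid cells and platelets, the median, the mean and the direction of the test did not all have the same sign.

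The count of 3080 genes was 2011 without Ly6C-low replicate 2 and 1956 without Ly6C-low replicate 3, and 2038 when only the 6 arrays of these groups were fitted. Under quantile normalization 41.7% and under cyclic loess 43.9% of the calls were higher in Ly6C-high microglia, against 29.1% on the deposited values.

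**Figure D2:**
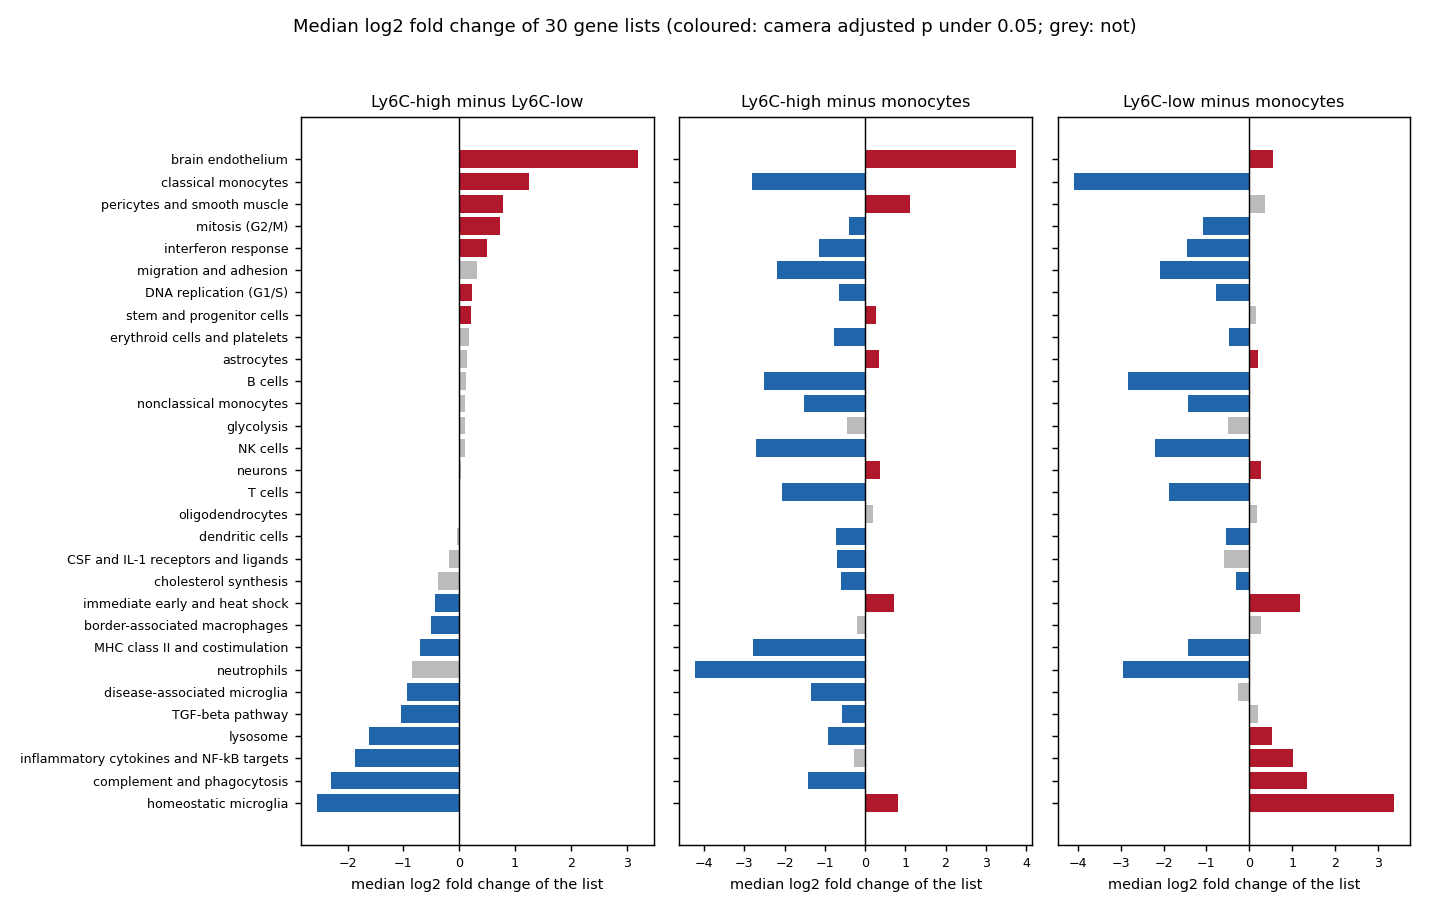
Median log2 fold change (horizontal axes) of each of the 30 gene lists (vertical axis) in the 3 comparisons, with red bars above 0 and blue bars below 0 for a camera adjusted p under 0.05 and grey bars for no call. The brain endothelium median was 3.20 against Ly6C-low microglia and 3.75 against monocytes, and the homeostatic microglia median -2.55 and 0.81.

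The comparison of Ly6C-high microglia with spleen monocytes asks how far the subset lies from monocytes, which also carry Ly6C. Ly6C-high microglia were higher in all 19 brain endothelium genes and in 11 of 23 homeostatic microglia genes, and lower in 10 of 11 MHC class II, 12 of 15 neutrophil and 10 of 18 classical monocyte genes. Ttr, the thyroid hormone carrier transthyretin made by the choroid plexus, led with 12.61 ± 0.31 against 5.17 ± 0.40 (log2 fold change 7.44 ± 0.32, 174-fold, adjusted p = 4.70e-06). In all 4290 genes passed, 1371 higher and 2919 lower, 2448 of them by at least 2-fold. The arrays of the groups did not overlap for 45.9% of genes, against 10% by chance.

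After Ttr came Slco1a4 (7.22 ± 0.63), Slco1c1 (6.56 ± 0.39), Car4 (6.32 ± 0.27) and Emcn (6.18 ± 0.21), then the matrix protein gene Sparcl1 (5.90), the tight junction gene Tjp1 (5.44), Itm2a (5.38), Mfsd2a (5.15), Adgrf5 (5.11), the growth factor gene Ptn (5.11) and Prom1 (32.0-fold). The endothelium list had a median of 3.75 (camera adjusted p = 2.39e-18, 0.120 with an estimated correlation), with Cldn5 at 4.68, and all 19 genes passed over the list alone. Among pericyte and smooth muscle genes 6 of 13 rose, including Rgs5 (4.56), Vtn (3.77) and the smooth muscle actin gene Acta2 (2.62) (adjusted p = 4.67e-04, 0.294 with an estimated correlation). In the homeostatic microglia list Sparc was higher by 3.15, Tmem119 by 2.43, Gpr34 by 2.27 and the purinergic receptor P2ry12 5.65-fold, while the growth factor receptor Csf1r was lower (-0.70; list median 0.81, adjusted p = 1.27e-05, 0.242 with an estimated correlation). Immediate early and heat shock genes had 9 of 21 higher, such as Hspa1a (2.86), Egr1 (1.87) and Jun (1.81) (adjusted p = 4.01e-05, 0.248 with an estimated correlation). Higher calls were also made for astrocytes (4 of 11 genes up, Gja1 2.16), neurons (2 of 13 up, Stmn2 1.73) and stem and progenitor genes (8 up and 4 down of 20, Prom1 and Cd34 3.75 among the higher), with adjusted p = 0.0038, 0.0120 and 0.0364, and 0.215, 0.272 and 0.159 with an estimated correlation. The stem and progenitor call ended without Ly6C-high replicate 2 (median 0.42, adjusted p = 0.0638), and without that array and Ly6C-low replicate 3 together. The neuron call ended under quantile normalization, under cyclic loess and with the description number as a block. Adjusted over the list alone, 12 microglia, 9 pericyte, 12 immediate early, 5 astrocyte, 2 neuron and 8 stem and progenitor genes were higher, and 1 microglia, 1 pericyte and 4 stem and progenitor genes lower.

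The genes that fell most were Prg2, an eosinophil granule protein gene (-6.02 ± 0.34), Retnlg (-5.83 ± 0.64), Spic, a transcription factor of spleen macrophages (-5.74 ± 0.23), an immunoglobulin kappa variable segment (-5.51), Car1 (-5.48), the MHC class II genes H2-Ea (-5.26) and H2-Aa (-5.07), P2ry10 (-5.26), Treml4 (-5.18), Adgre4 (-5.11), the neutrophil granule gene Ngp (-5.03) and the B cell receptor gene Cd79a (-4.96), with adjusted p from 2.58e-06 to 0.0058. The classical monocyte list had 10 of 18 genes lower, such as Plac8 (-3.67) and Chil3 (-3.58), and the transcription factor gene Klf2 higher by 1.47 (median -2.80, adjusted p = 8.12e-05, 0.294 with an estimated correlation), and of 12 nonclassical genes 8 were lower (Treml4; the integrin Itgal -3.63; median -1.52, adjusted p = 8.11e-06, 0.0926 with an estimated correlation). MHC class II and costimulation genes had 10 of 11 lower (median -2.79, with Cd74 at -4.31), migration and adhesion genes 11 of 14 lower and Cx3cr1 higher by 0.56 (median -2.19, with Itga4 at -3.15), and interferon response genes 12 of 21 lower (median -1.15, with Oas2 at -2.49). Markers of other spleen cells were lower in the same direction: B cells 10 of 11 (median -2.51), T cells 11 of 13 (-2.06), NK cells 7 of 13 (-2.72), neutrophils 12 of 15 (-4.21), dendritic cells 5 of 9 (-0.71), and erythroid cells and platelets 4 of 9 (-0.76). Lower calls were also made for CSF and IL-1 genes (7 of 11, median -0.70, with Il34 higher), disease-associated microglia (12 of 20, -1.34, Ccl6 -3.51, with Trem2 higher), lysosome (11 of 20, -0.92), TGF-beta pathway (6 of 12, -0.57), complement and phagocytosis (9 of 16, -1.42, with the ligand Gas6 and Trem2 higher), DNA replication (5 of 27, -0.64), cholesterol synthesis (6 of 16, -0.60, with Stard4 higher) and mitosis (0 of 29, -0.40). Adjusted p-values of the lists called lower ran up to 0.0249, and with an estimated correlation from 0.0926 to 0.604, so no call held there. Adjusted over the list alone, 14 classical and 8 nonclassical monocyte, 11 MHC class II, 11 migration, 15 interferon, 10 B cell, 12 T cell, 8 NK cell, 13 neutrophil, 5 dendritic, 14 disease-associated, 16 lysosome and 9 complement genes were lower. The mitosis call ended without Ly6C-high replicate 1 (median -0.30, adjusted p = 0.209) or 3 (-0.13, 0.306) and without monocyte replicate 1 (-0.21, 0.147) or 2 (-0.32, 0.0893). The complement call ended without Ly6C-high replicate 1 (-1.14, 0.0522) or monocyte replicate 3 (-1.34, 0.0586). The TGF-beta and complement calls ended under quantile normalization and cyclic loess, and the lysosome call under cyclic loess. The mitosis and complement calls also ended with the description number as a block. The gene calls of Plac8 and Chil3 were lost in 12 and 10 of 21 alternatives. No call was made for border-associated macrophages (4 up and 5 down of 13, median -0.20), oligodendrocytes (1 up and 1 down of 13, 0.19), inflammatory genes (3 up and 7 down of 22, -0.28) and glycolysis (1 up and 3 down of 12, -0.45). The count of 4290 genes was 2505 without monocyte replicate 1 and 2511 without monocyte replicate 2. Under quantile normalization 46.4% and under cyclic loess 45.0% of the calls were higher in Ly6C-high microglia, against 32.0% on the deposited values.

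The comparison of Ly6C-low microglia with spleen monocytes sets bulk microglia against a blood-derived myeloid cell. Ly6C-low microglia were higher in 22 of 23 homeostatic microglia genes (median log2 fold change 3.39) and lower in 15 of 18 classical monocyte genes (median -4.09). Of 21 immediate early genes 15 were higher in Ly6C-low microglia, and of 21 interferon response genes 16 were lower, a list call that also held with an estimated correlation (adjusted p = 0.0316). In all 2894 genes passed, 1356 higher and 1538 lower, 1752 of them by at least 2-fold. The arrays of the groups did not overlap for 42.3% of genes, against 10% by chance.

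Ttr again led, at 12.50 ± 0.58 against 5.17 ± 0.40 (7.33 ± 0.32, 161-fold, adjusted p = 4.61e-06). Tmem119 followed with 11.94 ± 0.32 against 6.24 ± 0.21 (5.70 ± 0.29, 52.0-fold), then Ccl12 (5.69), Fcrls (5.57), Gpr165 (5.53), Tanc2 (5.40), Plxdc2 (5.39), the metalloprotease gene Adamts1 (5.26), Gpr34 (5.21), Gal3st4 (4.99), Tjp1 (4.96) and P2ry12 (4.95). All 23 homeostatic microglia genes passed when adjusted over the list alone (camera adjusted p = 1.04e-27, 0.0486 with an estimated correlation, where the call held). Immediate early and heat shock genes had 15 of 21 higher and none lower (median 1.18, Hspa1a 2.97, Jun 2.25), inflammatory genes 13 of 22 higher and 1 lower (median 1.01, with Il1a at 3.59, Tnf at 2.95 and Ccl5 at -4.18), complement and phagocytosis genes 8 of 16 higher (median 1.36, Trem2 3.68, Mertk 3.60) and lysosome genes 9 of 20 higher (median 0.52, Ctsd 2.21). Their camera adjusted p-values were 1.01e-11, 1.60e-04, 2.25e-04 and 6.25e-04, and with an estimated correlation adjusted p = 0.119, 0.224, 0.224 and 0.402. Brain endothelium genes had 5 of 19 higher (median 0.55, Eng 1.94, Cldn5 1.49; adjusted p = 4.36e-04, 0.402 with an estimated correlation). Astrocyte genes had 2 of 11 higher (Slc1a3 2.71, S100b 1.18) and neuron genes 3 of 13 (Eno2 1.31, Snap25 1.17), with adjusted p = 0.0185 and 0.0129, both 0.265 with an estimated correlation. The astrocyte call ended without Ly6C-low replicate 1 (median 0.16, adjusted p = 0.0585), and the neuron call with the description number as a block. The S100b call was lost in 11 of 20 alternatives and the Cldn5 call in 7 of 21, among them both replicate blocks. In these lists 20 immediate early, 13 inflammatory, 9 complement, 10 lysosome and 6 endothelium genes were higher when adjusted over the list alone, and 3 inflammatory genes and 1 complement gene lower.

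The genes that fell most were Plac8 (-6.09 ± 1.10, adjusted p = 0.0065), Cytip (-5.81 ± 1.06), Car1 (-5.68 ± 0.23), Spic (-5.61 ± 0.23), an immunoglobulin kappa variable segment (-5.58), Adgre4 (-5.47), Ifitm6 (-5.38 ± 1.34, adjusted p = 0.0291), P2ry10 (-5.35), Emb (-5.31), S100a4 (-5.23), Plbd1 (-5.17) and H2-Ea (-5.14). The classical monocyte list, with Mgst1 at -5.02 and the chemokine receptor Ccr2 at -4.21, had a camera adjusted p of 1.90e-11, with Klf2 higher by 1.22 (0.171 with an estimated correlation). Interferon response genes had 16 of 21 lower (median -1.45, Irf7 -3.43, adjusted p = 7.30e-15), nonclassical monocyte genes 6 of 12 (median -1.44, Treml4 -5.05, adjusted p = 1.93e-08) and B cell genes 11 of 11 (median -2.82, Ms4a1 -4.66, adjusted p = 7.30e-15). These 3 calls held with an estimated correlation (adjusted p = 0.0316, 0.0316 and 0.0390). T cell genes had 10 of 13 lower (median -1.87), NK cell genes 7 of 13 (-2.20), neutrophil genes 9 of 15 (-2.94), MHC class II genes 7 of 11 (-1.44, H2-Aa -4.80), migration genes 9 of 14 (-2.08, with 2 higher), dendritic cell genes 4 of 9 (-0.55), erythroid and platelet genes 3 of 9 (-0.47), cholesterol synthesis genes 4 of 16 (-0.32), DNA replication genes 8 of 27 (-0.78, Rrm2 -2.30) and mitosis genes 12 of 29 (-1.08, Top2a -2.76, a call lost in 9 of 21 alternatives). These lists had adjusted p up to 0.0092, and with an estimated correlation adjusted p from 0.0571 to 0.256. When adjusted over the list alone, 17 classical and 9 nonclassical monocyte, 18 interferon, 11 B cell, 11 T cell, 10 NK cell, 11 neutrophil, 10 MHC class II, 13 DNA replication and 18 mitosis genes were lower. No call was made for border-associated macrophages (4 up and 1 down of 13, median 0.28), pericytes (3 up and 1 down of 13, 0.36), oligodendrocytes (1 up of 13, 0.19), stem and progenitor cells (2 up and 2 down of 20, 0.17), TGF-beta pathway (3 up of 12, 0.21), CSF and IL-1 genes (1 up and 4 down of 11, -0.60), glycolysis (2 up and 4 down of 12, -0.50) and disease-associated microglia (median -0.26). Disease-associated microglia genes split into 6 higher (Trem2 among them) and 6 lower (Lgals3 -3.91, Clec7a -2.96). The count of 2894 genes was 1864 without monocyte replicate 1, 4614 when only these 6 arrays were fitted and 5738 with array weights.

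**Figure D3:**
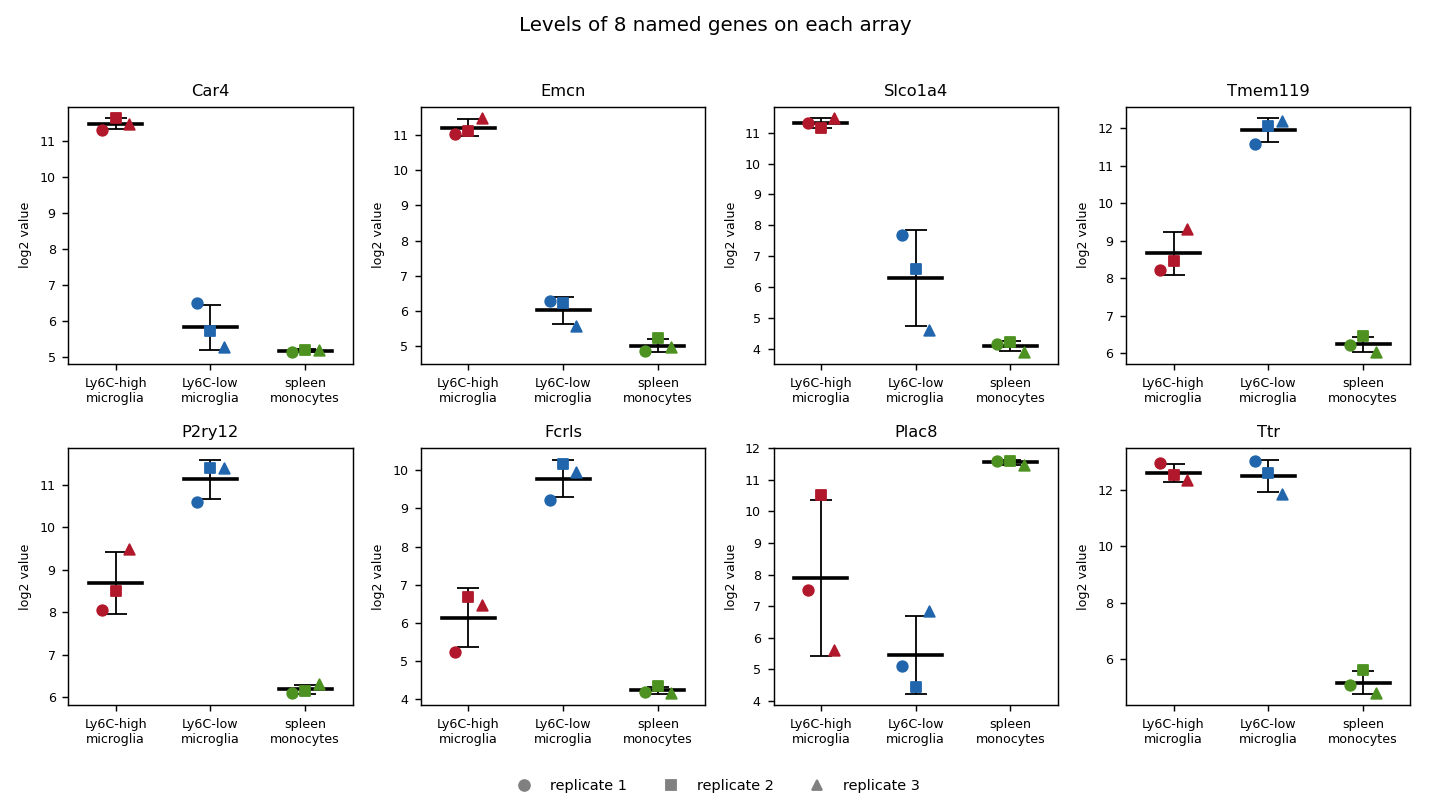
Log2 value (vertical axes) of 8 named genes on each of the 9 arrays, by group, with marker shapes for replicates, thick lines for group means and bars for the SD of 3 arrays. Car4, Emcn and Slco1a4 had means of 11.49, 11.21 and 11.32 in Ly6C-high microglia, Tmem119 and P2ry12 of 11.94 and 11.13 in Ly6C-low microglia, and Ttr of 12.61 and 12.50 in these groups.

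To place Ly6C-high microglia between the other groups, each gene at least 4-fold different between Ly6C-low microglia and monocytes was given a position, 0 at the Ly6C-low level and 1 at the monocyte level. The 233 genes higher in Ly6C-low microglia had a median position of 0.767, most of the way to the low monocyte level, while the 378 genes higher in monocytes had a median of 0.141. Any arrays with little RNA of the 233 genes would lie near 1 on that side, so 0.767 alone does not show a shift toward monocytes. The monocyte arrays also carried markers of other spleen cells, so these 378 need not all be genes of monocytes. Their list means were 8.73 for B cells and 7.78 for T cells, against 5.66 and 5.81 in Ly6C-low microglia. By Ly6C-high replicate the microglia genes gave 0.81, 0.78 and 0.65 and the monocyte genes 0.11, 0.40 and 0.03. Simulated groups in which Ly6C-high microglia had the Ly6C-low mean gave means of 0.013 and 0.009. The median of the monocyte genes was 0.0601 without Ly6C-high replicate 2 and 0.223 without replicate 3. Ly6C-high microglia and monocytes were both higher than Ly6C-low microglia for 262 genes and both lower for 864, against 69.0 and 149 for independent lists. The 864 carry the same limit as the position of the microglia genes. The simulated groups gave 3.71 and 3.08, but few calls could arise there, as the microglia groups were simulated without a difference. Those values therefore do not measure how much of 262 and 864 comes from the shared Ly6C-low arrays. The covariance of the 2 sets of fold changes across genes was 0.191, against 0.0207 simulated, and their correlation 0.358 against 0.0890. With 3 Ly6C-low arrays the shared controls could not be split into 2 sets of at least 2 arrays, so part of the excess may come from them, and genes are not independent replicates.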

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

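The tests of dividing microglia, endothelial cells in the Ly6C-high sort and monocytes in the Ly6C-low sorts, and the matched draws of shares were chosen after the result was seen, and all 3 patterns were noticed in the data. Groups of 3 arrays are too small for a test of outlying samples. Outside the gene table, 508 of the 13120 probe sets without a single gene symbol passed the threshold between Ly6C-high and Ly6C-low microglia, 103 higher and 405 lower.

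Brain endothelium genes were higher and homeostatic microglia genes lower in Ly6C-high than in Ly6C-low microglia. A narrower value range of the Ly6C-high arrays is argued against, because the highest median of 10000 gene lists matched on expression was 0.37 against 3.20 for the endothelium list, and the lowest -0.98 against -2.55 for the microglia list. Brain endothelial cells in the Ly6C-high sort stay open as a candidate source: that 18 of 19 list genes were higher, the most abundant being Slc2a1 at 12.15, Flt1 at 11.66 and Cldn5 at 11.41 (Slc2a1 is also in the glycolysis list), is the pattern itself and cannot decide it. A gate on CD45, CD11b and F4/80 would remove such cells, but the labels name these antibodies and not the gate, and against Ly6C-low arrays Adgre1 was 11.2-fold and Itgam 7.06-fold lower, while Ptprc did not pass (2.76-fold lower, adjusted p = 0.101, with replicate 2 at 9.99 against a Ly6C-low mean of 10.02). Microglia that carry endothelial transcripts of their own and fewer microglia transcripts cannot be told apart from such a mixture in bulk RNA, where a median of 8.83% of the excess of the 233 microglia genes over monocytes was kept on the linear scale.

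The means of the classical monocyte and mitosis lists were highest in Ly6C-high replicate 2 among the Ly6C-high arrays. The scaling or range of that array is argued against, because the highest median excess of 10000 matched lists was 0.98, below that of the classical monocyte list, and 0.26 against 1.28 for the mitosis list. Monocytes in that sort are a candidate source: of 360 genes higher in the monocyte arrays and outside both lists, 61.4% were highest in replicate 2, against 27.3% of all genes and at most 45.8% in 10000 matched draws. A gate on F4/80 or on the level of CD45 might remove monocytes, but the labels do not give the gate. Ptprc, which encodes CD45, was at 11.43 to 11.61 in the monocyte arrays and 9.68 to 10.23 in the Ly6C-low arrays. That difference did not pass the limma test (adjusted p = 0.0963). Gates on the mere presence of CD45, CD11b or Ly6C would not remove monocytes. The most abundant genes of the classical monocyte list, Lyz2, Ifitm3 and S100a6, were at 12.68, 12.38 and 12.18 in replicate 2. Ifitm3 was high in every Ly6C-high replicate, so these levels alone do not single out that sort. Other lists hold Ccr2, Itga4 and Lyz2 of that list. Whether dividing microglia added to the mitosis genes, with a median excess of 1.28, stays open, since the monocyte arrays also carried them. The mitosis list mean of 7.01 in replicate 2 was above those of the monocyte arrays (6.08 to 6.92, SD 0.45). Monocytes like those of the spleen arrays therefore need not account for all of it, but 1 array cannot decide this.

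The Ly6C-low arrays differed from one another in the Ly6C probe sets and in brain endothelium genes. Scaling is argued against, because the highest median difference of 10000 matched lists was 0.25 against 1.39 for the endothelium list. Endothelial or other Ly6C-high cells in the Ly6C-low sorts are a candidate source: of 216 further genes higher in Ly6C-high arrays, 71.3% ordered replicate 1 above 2 above 3, against 20.7% of all genes and at most 29.2% in 10000 matched draws, though the list means of pericytes and smooth muscle (SD 0.43), oligodendrocytes (0.21) and astrocytes (0.20), and less widely T cells and stem and progenitor cells, had that order too. For the endothelium genes, monocytes in those sorts are argued against. That list had means of 6.39 to 6.42 in the monocyte arrays, none above the Ly6C-low replicates (7.78, 7.20 and 6.43). For the Ly6C probe sets the classical monocyte list does not decide it. Its median difference, replicate 1 minus replicate 3, was -0.50, opposite to the pattern, with an SD of 1.29 over members that went both ways. Replicate 3 also had the highest neutrophil list mean (8.87 against 6.44 in replicate 1). No biological explanation was tested.

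With 3 arrays against 3 there are 10 splits of the arrays, too few for a share under 0.05. The real split was in each comparison the 1 with the most genes: 3080, 4290 and 2894 genes for Ly6C-high against Ly6C-low, Ly6C-high against monocytes and Ly6C-low against monocytes, with 0 in the highest of the other splits each time. All other splits mix the groups, so the group difference enters their spread. Low counts there follow from that difference and add no separate support.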

How the results depend on the processing

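Of the tests below, those with 2 arrays left out and with group variances were chosen after seeing the data. No called gene, list or value reversed under any alternative, by the direction of its test. Of 339 called results for named genes, 298 to 339 kept their direction and side of the threshold under each setting that tested all of them, as did 49 of 101 in the block of 4 arrays. Of 64 list calls 55 or more did so under every setting other than an estimated correlation (4) and dim genes left out (52 of 62). With a 2-fold minimum the counts were 1845, 2448 and 1752 for Ly6C-high against Ly6C-low, Ly6C-high against monocytes and Ly6C-low against monocytes, fewer by construction. Of other settings the cause was not tested. For Ly6C-low microglia against monocytes, fits of 2 groups only gave 4614 genes, array weights 5738 and group variances 5175. For Ly6C-high against Ly6C-low microglia, fits of 2 groups only gave 2038 genes, the unmoderated test 573 and group variances 2145. For Ly6C-high microglia against monocytes, the unmoderated test gave 1073 and group variances 3046. Leaving out 1 array gave 1956 to 3888, 2505 to 6091 and 1864 to 3778 genes, and 0.36 to 2.16 for the classical monocyte list median of Ly6C-high against Ly6C-low microglia, lowest without Ly6C-high replicate 2. Without Ly6C-high replicate 2 and Ly6C-low replicate 3 together the counts were 2463, 4911 and 2441. Cyclic loess moved the position of the microglia genes to 0.651. With an estimated correlation 0, 0 and 4 lists kept their calls, of 16, 26 and 22. The medians are the same by construction (-2.55, 1.25, 3.20 and 0.73 for homeostatic microglia, classical monocytes, brain endothelium and mitosis in the first comparison, 0.81 and -2.80 for the former 2 against monocytes, and -4.09 for classical monocytes in Ly6C-low microglia). With fry, 11, 24 and 25 lists were called, and 9 calls ended. In the first comparison these were classical monocytes (1.25, adjusted p = 0.158), mitosis (0.73, 0.208), DNA replication (0.436), MHC class II (0.124), immediate early genes (0.124) and pericytes (0.158). The others were mitosis (0.368) and complement (0.0970) for Ly6C-high microglia against monocytes and lysosome (0.0531) for Ly6C-low microglia. With dim genes left out 10 calls ended: border-associated macrophages, MHC class II and immediate early genes in the first comparison. In the second they were complement, cholesterol synthesis, DNA replication, mitosis, and erythroid cells and platelets, and in the third astrocytes, and erythroid cells and platelets. The neuron list had no genes left there. The median of all genes moved by less than 0.1 under each scaling.

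Groups share replicate numbers, but the title numbers do not pair the samples: deviations of same-numbered Ly6C-high and Ly6C-low arrays correlated at 0.30, 0.15 and -0.03 by title, with -0.07 to 0.05 for pairs with monocytes, and not every array was closest to its own number's partner. By description number only 2 pairs were shared, too few to settle a pairing, with correlations of 0.30 and 0.21, and each of these 4 arrays correlated best with its own number's partner. With the title number as a block 2973, 4295 and 2795 genes passed. With the description number as a random block (consensus correlation 0.29) the counts were 3936, 4286 and 2937, and 6 list calls ended: MHC class II and DNA replication between the microglia groups, complement, mitosis and neurons for Ly6C-high microglia against monocytes, and neurons for Ly6C-low microglia against monocytes. A block on the 4 arrays with shared description numbers gave 394 genes, with fewer arrays in the fit.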

Other observations

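Genes that set Ly6C-high microglia apart from both other groups were looked at after the data were seen, ranked by the smaller of the 2 changes. Beyond the genes already named, the adhesion receptor gene Adgrl4 was 4.06 above Ly6C-low microglia and 4.38 above monocytes on the log2 scale, Ccdc141 4.06 and 4.53 and the chemokine gene Cxcl12 4.26 and 3.98. Below both groups were Ms4a6d (-3.13 and -4.24), the cytokine gene Il18 (-2.88 and -3.22), the interleukin receptor genes Il21r (-2.67 and -2.74) and Il10ra (-3.56 and -2.58), the endosomal receptor gene Tlr13 (-2.92 and -2.61), the adaptor genes Dapp1 (-3.23 and -2.83) and Fyb (-2.58 and -2.91) and the NF-kB inhibitor gene Nfkbie (-2.63 and -2.73).

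The excess of Ly6C-high arrays over monocytes on the linear scale, as a percent of the Ly6C-low excess, differed between microglia genes. These arrays also carried the brain endothelium list at means from 10.11 to 10.65, so a percent is not a share of microglia expression. It had a median of 8.83% over 233 genes with quartiles of 2.15% and 25.3%, and per Ly6C-high replicate 6.79%, 7.30% and 13.4%. Among the 19 homeostatic microglia genes in that set the median was 9.07%, among 7 complement genes 5.62% and among 5 inflammatory genes 6.86%, while 5 immediate early and heat shock genes had 65.9%. Ttr had 105% and Tjp1 145%, above the Ly6C-low level, Sparc 68.7% and Adamts1 47.9%, against 9.05% for Tmem119 and 10.6% for Gpr34. A test of whether all microglia genes had lost a common share was run and set aside after its result was seen, because Sparc and Ttr went against it. RNA of other cells in these arrays could raise such genes, so Sparc and Ttr do not decide the question. The percents are given as values only.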
